A study of Mus musculus with 4 samples.

How the data were processed

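Single-cell RNA sequencing libraries were made from γδ T cells of the skin of wild-type mice. Per the labels, cells from 30 pooled mice were sorted by flow cytometry into dermal γδ T cells, dendritic epidermal T cells (DETC) and a population named GD3, and each population was loaded into its own channel of a droplet device with a 5' gene expression kit. The labels do not say what GD3 stands for or how it was gated. The 4 libraries are called dermal, GD3 A, GD3 B and DETC here. The labels do not say whether A and B came from separate sorts, channels or pools of mice. They were treated as 2 libraries of 1 pool, so the spread between them was not taken as a spread between animals. With 1 library each of dermal cells and DETC, differences between populations have no replicate check, and no p-values or standard errors are given.

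The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode for 32285 gene identifiers, made by the authors with Cell Ranger 6.1.2 on the mm10 build, per the submitters' processing notes. The annotation release and the use of strand in counting are not given in the sources used here. Gene positions came from the GENCODE vM21 annotation of GRCm38, in which 32235 of the identifiers were found and 50 were not. All barcodes were present in the matrices, from 330321 in the dermal library to 431544 in GD3 B, so cells were called here. The 99th percentile of the UMI totals of the 3000 largest barcodes was divided by 10, and barcodes at or above that value, and at or above 500 UMIs, were taken as cells. The resulting minima were 1482 UMIs in dermal, 1547 in GD3 A, 1603 in GD3 B and 1543 in DETC, and left 4646, 7481, 8506 and 7742 barcodes. Cells needed at least 200 genes, which removed 1 dermal barcode, and at most 10% mitochondrial UMIs, which removed 0, 3, 2 and 5 barcodes in the same order. Scrublet, run per library in scanpy 1.11.5, marked 1, 1, 1 and 0 barcodes as doublets. At a share of at most 0.0215% of a library this caller did not work, so doublets remain in the data.

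The remaining 4644 dermal, 7477 GD3 A, 8503 GD3 B and 7737 DETC cells were clustered together without batch integration, since library and population are the same thing here. Counts were log-normalised, and 2000 variable genes without T cell receptor (TCR), mitochondrial and ribosomal protein genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2) were used. Clusters were called T-like from marker lists fixed beforehand. A cluster was left out when its summed markers of other cell types passed 3000 counts per 1000000 UMIs (CPM), a limit set after the clusters were seen. The clusters left out held 0.668% of dermal, 0.843% of GD3 A, 0.588% of GD3 B and 0.478% of DETC cells. Clusters of which at least 70% of cells came from 1 population, with populations weighted equally, were called dermal-dominated (clusters 5, 8, 10, 14 and 17), GD3-dominated (clusters 0, 2, 3, 6, 7 and 13) or DETC-dominated (clusters 1 and 4). The others, 9, 11, 12 and 19, were mixed. Because each population is a library of its own, such a cluster may be the library and not a cell type, so the shares of cells per cluster group describe the libraries, and no cluster was named as a cell type beyond T-like.

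UMIs of the T-like cells were summed per library, giving 24340940 UMIs for dermal, 37423634 for GD3 A, 40244767 for GD3 B and 35662598 for DETC, and divided by these totals to give CPM. A count of 0 was set to a floor of 3 counts per library, which equals 0.123, 0.0802, 0.0745 and 0.0841 CPM in that order. Counts under the floor but over 0 were kept, so a gene with 0 UMIs could get a smaller fold than a gene with 1. A gene was counted as higher or lower when every library of the first population lay at least 2-fold to the same side of every library of the second, with at least 50 UMIs in each library of the higher population. Intervals are exact 95% intervals, Poisson for sums, Clopper-Pearson for shares and conditional binomial for ratios, and they cover counting error only. Ranges given for GD3 are the values of GD3 A and GD3 B. Background was read from barcodes with at most 100 UMIs: keratin and globin genes stood at 408, 1307, 836 and 477 CPM there against 18.0, 7.59, 5.54 and 8.83 CPM in the T-like cells of dermal, GD3 A, GD3 B and DETC. The ratio of these levels puts the background at 4.41%, 0.581%, 0.662% and 1.85% of UMIs. In dermal the 2 gene groups disagreed: erythroid genes alone stood at 277 CPM in these barcodes against 0.205 CPM in T-like cells. The dermal background, and the subtraction that used it, are therefore uncertain.

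Genes were named by a rule fixed before the data were examined, as were the comparisons, the gene lists, the cell markers and the size rule. The rule took, per comparison and direction, the 12 genes with the largest fold among those past the size rule with at least 100 UMIs in each library of the higher population, ranked by the smaller of the A and B folds. Mitochondrial, ribosomal protein, TCR segment, predicted and non-T marker genes were left out of that ranking, as were genes under 2-fold after subtraction of the background. It also took the 15 genes with the largest smaller fold among those higher in GD3 than in both other populations. Il3, every gene of the TCR γ and δ lists, and up to 4 members of each list with the largest folds were taken too. A few genes that the rule took are not reported here by name. The lists were study cytokines (IL-3 and other cytokines and chemokines), type 17, DETC programme, cytotoxic, early response, TCR signalling, residency and trafficking, transcription factors, cytokine receptors, neuropeptide receptors, co-receptors and checkpoints, cell cycle, interferon response, glycolysis, lipid, TCR γ variable, TCR γ constant and TCR δ genes. Some genes stand in several lists. A member counted as measured with at least 20 UMIs over the libraries compared. Each list's median log2 fold, with counts of 0 at the floor, was placed among 10000 random lists of the same size matched on mean expression, which describes these libraries only. Marker lists of T cells, γδ T cells, αβ T cells, NK cells and innate lymphoid cells, keratinocytes, fibroblasts, macrophages and monocytes, Langerhans and dendritic cells, mast cells, basophils, B and plasma cells, neutrophils, endothelium, melanocytes and Schwann cells, muscle and pericytes, and erythroid cells were summed likewise.

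A variable gene was called dominant in a cell when it held at least 80% of the cell's UMIs of the γ (or δ) variable genes. Only genes named Trdv were counted as δ variable genes, so any δ chain with another variable gene was not counted. TCR variable genes resemble one another and share reads, so their levels are uncertain where the counting could split them. The same holds for Klr family genes and for Hspa1a and Hspa1b. Trdv5 lies on the minus strand of chromosome 14 at 54148662 to 54149294 and overlaps the annotated end of Trdc on the plus strand (54142851 to 54148868), and Kirrel3os is annotated as antisense. Counts of these genes are uncertain without knowledge of strand use. To set shares of cells beside each other, cells were thinned to 1450 UMIs.

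The computation of folds and intervals was tested on simulated data made from the libraries' own means. Counts were drawn with Poisson noise only, and changed genes had at least 100 expected UMIs in the smallest library compared. Recovery of the larger changes was thus near fixed in advance. In each of the 3 comparisons 50 of 50 genes changed 3-fold, 50 of 50 changed 5-fold and 50 of 50 changed 10-fold passed the size rule, and 0 of 50 changed 1.5-fold did. Among unchanged genes 1 passed of the 19600 simulated for GD3 against DETC, 0 of 19943 for GD3 against dermal and 0 of 19276 for DETC against dermal. These totals include genes too low to reach 50 UMIs, which could hardly pass. In the data 11085, 11324 and 11476 genes reached that minimum in the same order. GD3 A and B differed by more than Poisson noise, so these counts are no rate of false calls between real libraries. The intervals held the simulated ratio for 95.6%, 97.0% and 96.4% of 500 genes in the same order. The alternatives planned beforehand were UMI minima of 1000 and 500, mitochondrial limits of 5% and 20%, doublets kept, all called cells, cells with a Trdc UMI, background subtraction, TMM scaling (edgeR 4.0.16 in R 4.3.3), totals without mitochondrial and ribosomal protein genes, thinned cells, rule minima of 20 and 200 UMIs, a 3-fold rule, dominance at 50% and 100%, and each GD3 library left out. Alternatives added after the data were seen were removal of the 6% of barcodes with the highest Scrublet scores, a Tcrg-V5 gate that kept only cells with dominant Tcrg-V5 in DETC and removed them elsewhere, removal of proliferating clusters, and all alternatives for the comparison of variable gene classes within a library and for δ variable gene shares. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.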

Results

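The data were 4 droplet libraries of polyadenylated RNA from γδ T cells sorted from the skin of wild-type mice: 1 of dermal γδ T cells, 1 of DETC, the γδ T cells that reside in mouse epidermis, and 2 of GD3 cells, A and B. The series title concerns T cell IL-3 and the responses of sensory neurons to allergens. The matrices held 25090750 UMIs for dermal, 39065422 for GD3 A, 42005960 for GD3 B and 37375771 for DETC. After cell calling 4613, 7414, 8453 and 7700 T-like cells remained in the same order, with median depths of 4812, 4599, 4296 and 4125 UMIs and 1885, 1900, 1819 and 1847 genes per cell. Ribosomal protein genes took 17.9% of dermal UMIs, against 13.02% and 12.7% in GD3 A and B and 10.3% in DETC. Most dermal cells (93.3%) lay in clusters 5, 8, 10, 14 and 17, most GD3 cells (90.6% of A and 90.9% of B) in clusters 0, 2, 3, 6, 7 and 13, and most DETC cells (76.0%) in clusters 1 and 4. The GD3-dominated clusters also held 1156 DETC-library cells (15.01%, 14.2 to 15.8) and 290 dermal-library cells (6.29%).

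GD3 A and GD3 B gave the size of difference that separate libraries of 1 sorted population showed. Their log2 CPM had a Pearson correlation of 0.999 across genes, which are not independent replicates, and 11 of 10970 genes with at least 50 UMIs differed 2-fold. Under the alternative settings this number ranged from 0, with a minimum of 200 UMIs, to 110, with all called cells. The standard deviation of their log2 ratios was 0.157, against 0.489 and 0.494 for GD3 A and B each set against DETC and 1.72 to 1.73 for dermal against any of the others. Their counts differed by more than sampling noise, with a chi-square per degree of freedom of 5.02 against 1.23 and 1.26 between parts of the cells of B or of A. They shared 92 cell barcodes, with 91.9 expected by chance, and were kept as separate libraries. Every gene counted below as higher or lower in GD3 passed the size rule in A and in B.

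IL-3, the cytokine of the series title, is encoded by Il3 (ENSMUSG00000018914, chromosome 11, 54265303 to 54267277, minus strand, GRCm38). Il3 was found at trace level: 13 UMIs in 5 of 7414 GD3 A cells, 27 UMIs in 7 of 8453 GD3 B cells, 10 UMIs in 5 of 7700 DETC and 0 UMIs in 4613 dermal cells. These counts equal 0.347 CPM (0.185 to 0.594) in GD3 A, 0.671 CPM (0.442 to 0.976) in GD3 B and 0.280 CPM (0.134 to 0.516) in DETC. They changed with the choice of cells, to 0.251 CPM in GD3 B in cells with a Trdc UMI and 0.408 CPM in thinned cells, to 0.173 CPM in GD3 A without the top 6% of Scrublet scores and to 0.127 CPM in DETC without proliferating clusters. In dermal cells 0 UMIs allow up to 0.152 CPM, and 0 of 4613 cells allows a share of up to 0.0799% of cells with a detected Il3 UMI, which is no limit on the share of cells that transcribe the gene. The shares of cells with a UMI were 0.0674%, 0.0828% and 0.0649% in GD3 A, GD3 B and DETC, and 0.0405%, 0.0473% and 0.0390% after thinning. Droplets without cells held 1 Il3 UMI in GD3 A and 0 in the other 3 libraries, and the few cells outside the T-like clusters held 0. The intervals of these shares, 0.0219% to 0.157%, 0.0333% to 0.171% and 0.0211% to 0.151%, overlapped widely, and no difference between GD3 and DETC in the share of cells with Il3 was detectable at this depth. The higher sum of GD3 B rested on 7 cells and was not seen in GD3 A.

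The comparison of GD3 with DETC asked how the GD3 population differs from the epidermal γδ T cells. GD3 cells had 6.998- to 7.16-fold more Ntrk2 (ENSMUSG00000055254), which encodes the neurotrophin receptor TrkB, at 39.2 and 38.3 CPM in A and B against 5.47 in DETC. Gfra1 (ENSMUSG00000025089), which encodes a co-receptor for glial cell line-derived neurotrophic factor, was 7.20- to 8.40-fold higher, at 3.77 and 3.23 against 0.449 CPM. Tbx21 (ENSMUSG00000001444), the gene of the type 1 transcription factor T-bet, was 4.02- to 4.76-fold higher, at 16.9 and 20.03 against 4.21 CPM. DETC in turn had 11.9- to 13.2-fold more Lag3 (ENSMUSG00000030124), an inhibitory receptor gene, at 89.1 CPM against 6.76 and 7.50. A minority of cells held a UMI of these genes. In GD3 A, GD3 B and DETC the shares were 11.2%, 10.6% and 1.70% for Ntrk2 and 1.79%, 1.46% and 0.208% for Gfra1. They were 4.63%, 5.68% and 1.25% for Tbx21 and 2.75%, 3.19% and 27.4% for Lag3. Of 11085 genes measured, 121 were higher and 278 lower in GD3. These are folds over the whole DETC library. Its 1156 cells in GD3-dominated clusters, counted after the data were seen, held 13.7% of all DETC UMIs, but 56.9% of its Ntrk2, 68.8% of its 16 Gfra1 and 35.3% of its Tbx21 UMIs and 2.77% of its Lag3 UMIs. Ntrk2 stood at 22.7 CPM, Gfra1 at 2.25 and Tbx21 at 10.8 in these cells, against 2.89, 0.192 and 3.002 CPM in DETC-dominated clusters. Over the genes higher in GD3 with at least 20 DETC UMIs (108 genes) the median share in these cells was 27.8%, and 8 genes had over 50% there, against a median of 6.92% for the 278 lower genes. The cells were grouped by expression, so a contrast in this direction follows in part from how they were placed.

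The other genes named as highest in GD3 over DETC were Selenop (6.24- to 6.74-fold), Olfr523, Scin (4.42- to 4.49-fold), Csgalnact1, Nav1, Dzip1, Ly6a (3.85- to 3.87-fold), the chemokine receptor gene Ccr8 (3.83- to 4.07-fold) and Nptx1. Scin, which encodes an actin-severing protein, reached 124 and 125 CPM in GD3 against 27.9 in DETC, with 117 CPM in the DETC-library cells of GD3-dominated clusters and 9.43 CPM in DETC-dominated clusters. The counting intervals of both libraries spanned 6.03 to 8.36 for Ntrk2, 4.27 to 15.1 for Gfra1, 3.36 to 5.71 for Tbx21 and 10.6 to 15.05 for Lag3. Among genes higher in DETC, Lgi2 had 182 UMIs there (5.10 CPM) against 1 and 4 in GD3 A and B, with ratios whose counting intervals spanned 19.7 to 7585. Timp4, an inhibitor of metalloproteinases, was 39.0- to 50.3-fold higher in DETC, Myot 24.7- to 30.9-fold and the proton channel gene Otop1 12.6- to 22.8-fold. The rest of the 12 named for DETC were Jam2, Kirrel3os, Itih5, Col12a1, Gsta4, Trim52 and the potassium channel gene Kcnt2, from 9.75-fold upward.

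Of the fixed lists, the study cytokines had 1 member higher and 4 lower in GD3 than in DETC of 20 measured. The lower ones were Xcl1, a lymphotactin gene, at 427 and 414 against 1132 CPM, Il2 (2.46- to 2.50-fold), Osm (2.31- to 2.92-fold) and Il17a, whose 58 and 23 UMIs in A and B lay 3.51- and 9.52-fold under DETC. The call on Il17a, which also counts in the type 17 list, rests on 8 and 7 cells of A and B and 9 of DETC, shares of 0.108% (0.0466 to 0.213), 0.0828% (0.0333 to 0.171) and 0.117% (0.0535 to 0.222) whose intervals overlapped. Of the DETC programme 6 of 23 were lower and 0 higher, among them Cd160 (3.12- to 3.31-fold), Nrgn (2.93- to 3.11-fold) and Jaml (2.77- to 2.80-fold), which encodes a costimulatory junctional adhesion protein. The cytotoxic list gave 2 higher and 4 lower of 18, with Fasl 2.91- to 3.10-fold higher and Klrc1 3.46- to 3.51-fold lower. Cytokine receptors gave 1 higher and 4 lower of 23: Il6ra was 3.11- to 3.36-fold higher, and Il18r1 (8.06- to 8.20-fold), Il2ra (6.73- to 8.11-fold) and Il18rap (3.59- to 3.92-fold) were among the lower. The type 17 list had 2 higher and 3 lower of 18, with Ccr2 2.19- to 2.38-fold higher. Residency and trafficking genes numbered 2 higher and 4 lower of 22, including Cd69 (3.03- to 3.07-fold lower) and Gpr15 (2.60- to 3.17-fold lower). Co-receptors and checkpoints gave 2 higher and 3 lower of 15, with Havcr2, the gene of TIM-3, 2.41-fold higher in A and in B and Cd101 2.65- to 3.18-fold lower.

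Transcription factors gave 1 higher (Tbx21) and 2 lower of 26, one of them Id3 at 54.4 and 58.2 against 162 CPM. Early response genes gave 0 higher and 3 lower of 26: Hspa1b, Dusp2 (2.39- to 2.85-fold) and Hspa1a. Of TCR signalling genes 1 of 18 was lower, Cd28 (2.74- to 3.22-fold), and of neuropeptide receptors 1 of 6, Ramp1, which encodes a subunit of the receptor for calcitonin gene-related peptide (3.05 and 3.53 against 24.7 CPM). The interferon list had 1 member higher of 17, Oasl2 (2.03- to 2.30-fold). No member of the cell cycle list (21 measured), the glycolysis list (14) or the lipid list (22) passed the rule. The median of all genes was -0.13 on the log2 scale. List medians stood under it at -0.57 for study cytokines, -0.52 for type 17, -0.33 for the DETC programme, -0.26 for cytotoxic genes, -0.39 for co-receptors, -0.38 for cell cycle, -0.59 for neuropeptide receptors, -0.24 for transcription factors, -0.16 for cytokine receptors and -0.15 for glycolysis. Their percentiles among matched random lists were 0, 0.03, 0, 0.14, 0.12, 0, 0.4, 2.68, 19.7 and 4.53 in that order. Cytotoxic genes, transcription factors, cytokine receptors and glycolysis lay under the median of all genes by less than the shift that TMM scaling gave (0.14). The medians of early response (-0.07, percentile 14.9), TCR signalling (-0.06, 13.2), residency (-0.10, 52.8) and interferon genes (-0.08, 84.8) were of the size of the scaling shift. The lipid list stood at 0.14 (percentile 100), with 0 of its 22 measured members past the rule. Of markers of other cell types, keratinocyte genes summed to 118 and 110 CPM in GD3 A and B and 206 in DETC, with Sfn the most abundant. TMM scaling raised the median of all genes by 0.14 and moved the split from 121 higher and 278 lower (30.3% higher) to 150 and 208 (41.9% higher). There is 1 DETC library, so these differences compare libraries.

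**Figure D1:**
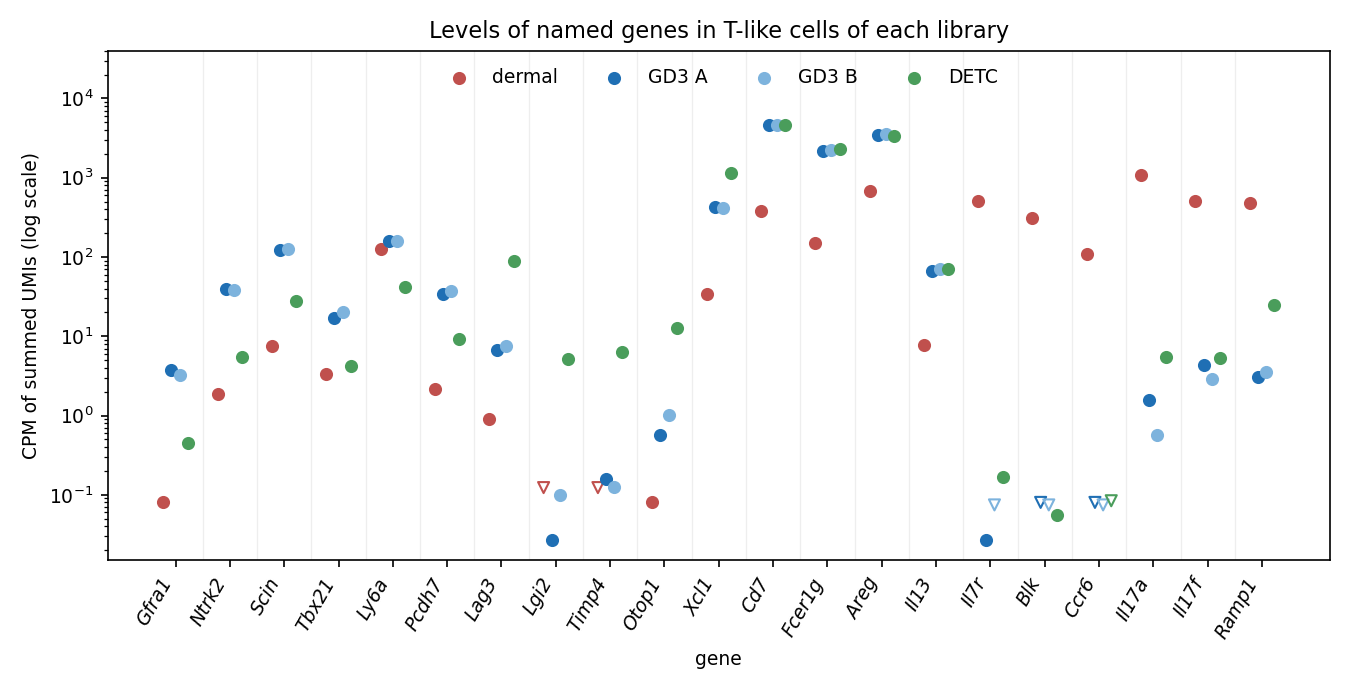
CPM of summed UMIs (log axis) of 21 genes in the T-like cells of each of the 4 libraries, 1 point per library, with open triangles at the floor of 3 counts where a library had 0 UMIs. Ntrk2 stood at 39.2 and 38.3 CPM in GD3 A and B against 5.47 in DETC and 1.89 in dermal cells, and Il17a at 1097 CPM in dermal cells against 5.44 or less elsewhere.

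The comparison of GD3 with dermal γδ T cells set the population against the cells of the deeper skin layer. Central genes of type 17 γδ T cells were at or near 0 UMIs in GD3. Blk (ENSMUSG00000014453), a kinase gene of the Src family, stood at 306 CPM in dermal cells against 0 UMIs in either GD3 library, at least 3822-fold lower. Il17a (ENSMUSG00000025929) was 708- and 1920-fold lower from a dermal level of 1097 CPM, and Il7r, the interleukin 7 receptor gene, had 12513 UMIs in dermal cells against 1 and 0 in GD3 A and B. Genes of natural killer type effector function went the other way, with Nkg7 16.8-fold higher in GD3 at 2351 and 2349 against 140 CPM and the perforin gene Prf1 13.5- to 13.9-fold higher. Of 11324 genes measured, 1876 were higher and 1554 lower in GD3.

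Besides Blk and Il7r, the genes named as lowest in GD3 included Pde4b, Pxdc1 (3416- and 5558-fold, from 594 CPM), Actn2, Sla, Tnfrsf25, the chemokine receptor gene Ccr6 (at least 1344-fold), Irak3 (at least 1306-fold), Mmp25 (at least 1195-fold) and Kcnk1 (at least 944-fold). Pde4b had 9783 UMIs in dermal cells against 4 and 1 in GD3 A and B. Part of the dermal UMIs of genes higher in GD3 came from 290 cells of the dermal library (6.29%) that lay in GD3-dominated clusters, a count made after the data were seen. These cells held 5.66% of all dermal UMIs, but a median of 18.7% of the dermal UMIs of genes higher in GD3 (1544 genes with at least 20 dermal UMIs, 235 of them with over 50% in these cells) and 1.49% for genes lower in GD3. They too were grouped by expression, so part of this contrast follows from how they were placed. The shares were 76.2% for Nkg7, 63.1% for Prf1, 78.8% for Cd244a, 72.2% for Ctla2a, 69.7% for Il13 and 71.7% for Lck. The folds given here are those of the whole library. Npffr1, which encodes a receptor for neuropeptide FF, had 213 and 216 UMIs against 1 in dermal cells, with ratios of 131 and 139 and counting intervals of 23.2 to 5497. Tspan7 was 49.3- to 53.5-fold higher, Nkpd1 33.0- to 34.9-fold and Alpk2 32.1- to 35.3-fold. Gfra1 had 2 dermal UMIs and ratios of 39.3 and 45.9 (10.7 to 382), and Bcam 3 dermal UMIs and ratios of 26.4 and 29.3 (8.84 to 144). Others were Gal3st1, Spns3, Tnfaip8l3 and Spaca9, at 23.7-fold or more in both libraries.

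Of the type 17 list 24 of 26 members were lower and 0 higher, with a median of -7.22 on the log2 scale. The cytotoxic list gave 13 higher and 0 lower of 18 (median 2.05), among them Fcer1g (14.4- to 14.6-fold) and Klrd1 (13.5- to 13.6-fold), of which the 290 cells held 78.6% and 76.9% of dermal UMIs (Fcer1g at 2108 CPM there and 20.4 CPM in dermal-dominated clusters), and the DETC programme 15 higher and 2 lower of 23 (median 2.96), with Cd244a 14.6-fold and Ctla2a 13.03- to 13.9-fold higher. Study cytokines gave 5 higher and 11 lower of 23 (median -1.40): Areg, which encodes the epidermal growth factor family member amphiregulin, stood at 3469 and 3537 against 678 CPM, Il13 was 8.60- to 9.16-fold higher, and Il17f (118- and 179-fold), Cxcl2 (63.6- and 131-fold) and Csf2 (3.48- to 3.68-fold) were lower. Areg, Il13 and Csf2 were singled out after their values were seen. Residency and trafficking genes gave 4 higher and 15 lower of 25 (median -2.96), with Cxcr4 177- to 292-fold lower. Transcription factors gave 4 higher and 14 lower of 30 (median -1.34), with Ikzf3 596- to 607-fold lower. Cytokine receptors gave 4 higher and 13 lower of 25 (median -1.73), with Il2ra 243- to 293-fold lower. Each of these 7 lists lay at percentile 0 or 100 among random lists.

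Of neuropeptide receptors 4 of 9 were lower and 0 higher (median -3.42, percentile 0), with Ramp1 136- to 157-fold lower. Co-receptors and checkpoints were divided, 8 higher and 8 lower of 16 (median -0.16, percentile 21.8), with Pdcd1, the gene of PD-1, 663- to 952-fold, Slamf1 476- to 553-fold, Cd226 107- to 116-fold and Icos 19.9- to 20.2-fold lower. TCR signalling genes gave 6 higher and 4 lower of 20 (median 0.58, percentile 94.1), with Lck 13.9- to 14.4-fold higher, Cd6 at least 121-fold lower, Cd5 31.7- to 42.6-fold lower and Cd27 22.5- to 24.2-fold lower. Early response genes gave 4 higher and 8 lower of 26 (median 0.22, percentile 74.4), among them Nfkbiz (23.8- to 26.1-fold lower), Nfkbia (9.37- to 9.50-fold lower) and Nr4a1 (6.44- to 6.69-fold lower). The interferon list had 2 higher and 7 lower of 21 (median -0.72, percentile 0.63), with Ifi203 21.5- to 24.3-fold lower, Gbp2 9.15- to 10.2-fold lower and Bst2 5.34- to 5.44-fold higher. Glycolysis gave 2 higher and 5 lower of 14 (median -0.61, percentile 0.18): the hexokinase gene Hk2 was 2.90- to 3.59-fold and Tpi1 3.02- to 3.07-fold higher, and the glucose transporter gene Slc2a3 16.2- to 16.96-fold and Pkm 2.43- to 2.49-fold lower. Lipid genes gave 5 higher and 4 lower of 23 (median -0.09, percentile 37.6), with Scd2 4.43- to 4.75-fold and Cyp51 3.79- to 3.81-fold higher and Acsbg1 11.3- to 13.3-fold and Dgat1 5.40- to 5.77-fold lower. In the cell cycle list 1 of 21 was higher, Pcna (2.34- to 2.37-fold), with a median of -0.18 (percentile 22.4). The median of all genes was -0.03.

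Summed markers of other cell types, in the order dermal, GD3 A, GD3 B and DETC, were as follows. T cell genes stood at 5544, 15371, 15437 and 16023 CPM, γδ T genes at 3755, 1295, 1255 and 8653 and αβ T genes at 289, 155, 160 and 176. NK and innate lymphoid genes stood at 733, 3532, 3597 and 3447, of which Areg alone gave 678, 3469, 3537 and 3340. Fibroblast genes stood at 54.1, 309, 313 and 336 CPM (Gsn alone at 50.5, 301, 307 and 278). Macrophage genes stood at 18.4, 94.9, 97.7 and 79.2 (Cd68 alone at 9.41, 93.8, 97.1 and 78.5). B and plasma cell genes stood at 15.6, 91.0, 88.9 and 128 (Ighm alone at 6.86, 74.2, 74.0 and 124). Keratinocyte genes were at 339 CPM in dermal cells, Langerhans and dendritic cell genes at 135, 84.8, 84.2 and 123, endothelial genes at 20.7, 5.80, 4.35 and 10.9, and muscle genes at 2.79, 7.94, 7.48 and 10.8. Mast cell (0.246, 0, 0 and 0), basophil (0, 0.160, 0.0745 and 0.561), neutrophil (2.01, 0.107, 0.248 and 0.112), melanocyte (0.370, 0.454, 0.248 and 0.645) and erythroid genes (0.205, 0.107, 0.273 and 0.112) summed to at most 2.01 CPM in any library.

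DETC were set against dermal γδ T cells as the γδ T cells of the epidermis and the dermis. DETC had 98.6-fold more Lag3 than dermal cells, 32.8-fold more Xcl1 and 25.0-fold more Cd160. The 290 dermal-library cells in GD3-dominated clusters held 40.9%, 65.6% and 54.1% of the dermal UMIs of these 3 genes, with Xcl1 at 401 CPM there and 9.14 CPM in dermal-dominated clusters. Dermal cells had 306 CPM of Blk against 2 UMIs in DETC, a ratio of 5463 (1512 to 45122), and 202-fold more Il17a. Of 11476 genes measured, 2198 were higher and 1404 lower in DETC.

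Genes named as highest in DETC included Kcnt2, Npffr1, Myot, Acsl6, Trim52, Kirrel3os, Otop1, Klrb1a, Prune2, Lag3 and Col12a1. Kcnt2 had 511 UMIs against 1 in dermal cells, a ratio of 349 (62.3 to 13803), and Npffr1 429 against 1, a ratio of 293 (52.3 to 11592). Those named as lowest included Blk, Irak3, Il7r (3056-fold, 1403 to 8328), Sox13, Kcnk1, Pde4b (2389-fold), Adam8, Slamf1, Cd226, Pxdc1 (1926-fold) and Actn2 (1681-fold). Irak3, Sox13, Kcnk1, Slamf1 and Cd226 each had 1 UMI in DETC. Since only counts of 0 were set to the floor, this ranking favours such genes. Slamf1, at 59.2 dermal CPM, had a ratio of 2110, while Ccr6, at 108 dermal CPM and 0 DETC UMIs, had 1281.

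The type 17 list gave 0 higher and 24 lower of 26 in DETC (median log2 fold -7.13). Of the DETC programme 17 of 23 were higher and 2 lower (3.09), with Nrgn 36.5-fold higher, and of cytotoxic genes 14 of 18 higher and 0 lower (2.49), with Nkg7 17.6-fold, Klrd1 16.8-fold and Prf1 14.8-fold higher. The 290 cells held 64.8%, 76.2%, 76.9% and 63.1% of the dermal UMIs of these 4 genes, with Nkg7 at 23.02 CPM in dermal-dominated clusters, so the folds over those cells alone would be larger. Study cytokines numbered 4 higher and 9 lower of 19 (-1.06), with Il22 116-fold and Il17f 96.2-fold lower. Residency genes gave 4 higher and 15 lower of 25 (-2.08), with Ccr6 at least 1281-fold, S1pr1 at least 579-fold and Cxcr4 245-fold lower. Transcription factors gave 3 and 14 of 30 (-1.09), with Ikzf3 642-fold and Runx1 637-fold lower, and cytokine receptors 4 and 13 of 24 (-1.65), with the interleukin 23 receptor gene Il23r 275-fold and Il1r1 171-fold lower. Neuropeptide receptors gave 1 higher and 4 lower of 9 (-4.06), with Ramp1 19.4-fold lower. Each of these 8 lists lay at percentile 0 or 100 among random lists.

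Co-receptors and checkpoints were again 8 higher and 8 lower of 16 in DETC (-0.19, percentile 10.1), with Pdcd1 907-fold lower. Interferon genes gave 2 and 7 of 21 (-0.65, 0.16), with Ifi27l2a 33.9-fold and Ifi203 33.2-fold lower and Isg15 5.75-fold higher, and TCR signalling genes 7 and 4 of 20 (0.77, 99.1), with Lck 15.1-fold and Cd2 5.38-fold higher and Cd6 with 2 DETC UMIs and a ratio of 174 to the dermal side. Early response genes gave 6 and 5 of 26 (0.19, 76.0), with Nr4a2 4.16-fold higher and Nfkbiz 14.4-fold and Nr4a1 4.68-fold lower. Glycolysis gave 2 and 2 of 14 (-0.49, 0.62), with Tpi1 3.04-fold higher and Slc2a3 13.5-fold lower, lipid 4 and 4 of 23 (-0.16, 8.77), with Scd2 5.88-fold higher and Acsbg1 14.2-fold lower, and cell cycle 1 and 0 of 21 (0.20, 76.5), with Pcna 2.27-fold higher. Without the proliferating clusters the cell cycle median turned to -0.36. The median of all genes was 0.12, and totals without mitochondrial and ribosomal protein genes shifted it by -0.12.

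**Figure D2:**
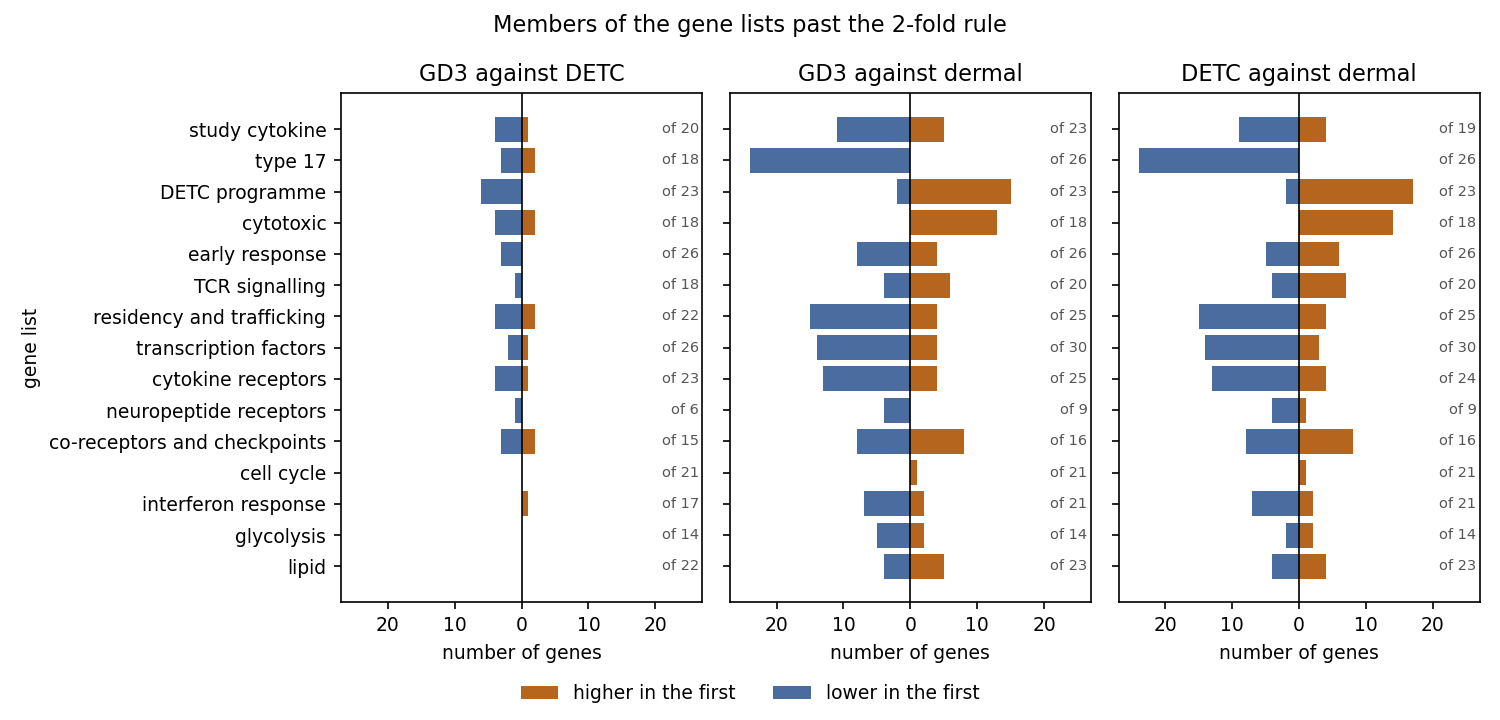
Number of members of each of the 15 gene lists past the 2-fold rule (horizontal axis, lower to the left and higher to the right) in the 3 comparisons, with the number measured at the right edge. The type 17 list had 24 of 26 members lower in GD3 and in DETC than in dermal cells, and no list had more than 6 members past the rule in 1 direction between GD3 and DETC.

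Some genes were higher or lower in the GD3 libraries than in both other populations. Of 10826 genes tested in both comparisons, 85 were higher in GD3 than in DETC and than in dermal cells, and 74 were lower than in both. Ntrk2 was 20.2- to 20.7-fold above dermal cells, Scin 16.4- to 16.7-fold, Pcdh7, a protocadherin gene, 15.7- to 17.04-fold and Tbx21 5.08- to 6.02-fold. In dermal-dominated clusters of the dermal library these 4 genes stood at 0.308, 0.879, 0.264 and 1.49 CPM, and in its 290 cells in GD3-dominated clusters at 25.4, 97.3, 34.1 and 30.5 CPM. In the DETC library the 148 cells with dominant Trdv5 held Ntrk2 at 50.6 CPM (35.04 to 70.7), Scin at 225, Gfra1 at 4.46 (0.921 to 13.05, 3 UMIs) and Tbx21 at 13.4 (6.12 to 25.4), against 3.29, 18.1, 0.332 and 3.86 CPM in the 7147 cells with dominant Trdv4, so these genes were not confined to the GD3 libraries. The others of the 15 named were Gfra1, Olfr523 (4.46- to 5.003-fold above DETC and 6.49- to 7.28-fold above dermal cells), Nptx1, Calml3, Mylk2, Col6a2, Csgalnact1, Dhx57, Tmem114, Shroom3 (3.10- to 3.16-fold and 15.8- to 16.1-fold) and Gramd3, with folds over DETC from 3.09 upward. Col6a2 turned to a log2 fold of -0.78 against dermal cells when all called cells were used. Of these 10826 genes, 121 were higher in GD3 than in DETC and 1876 than in dermal cells, and 191 and 1070 lower. Independent lists of these sizes would share 21.0 genes upward and 18.9 downward. In 20 simulations that drew all 4 libraries from the summed GD3 profile the means were 0.05 and 0. No library differed there, so these means were near fixed and do not measure the overlap that shared libraries cause. Both comparisons use the same GD3 libraries, so part of the excess may come from them.

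**Figure D3:**
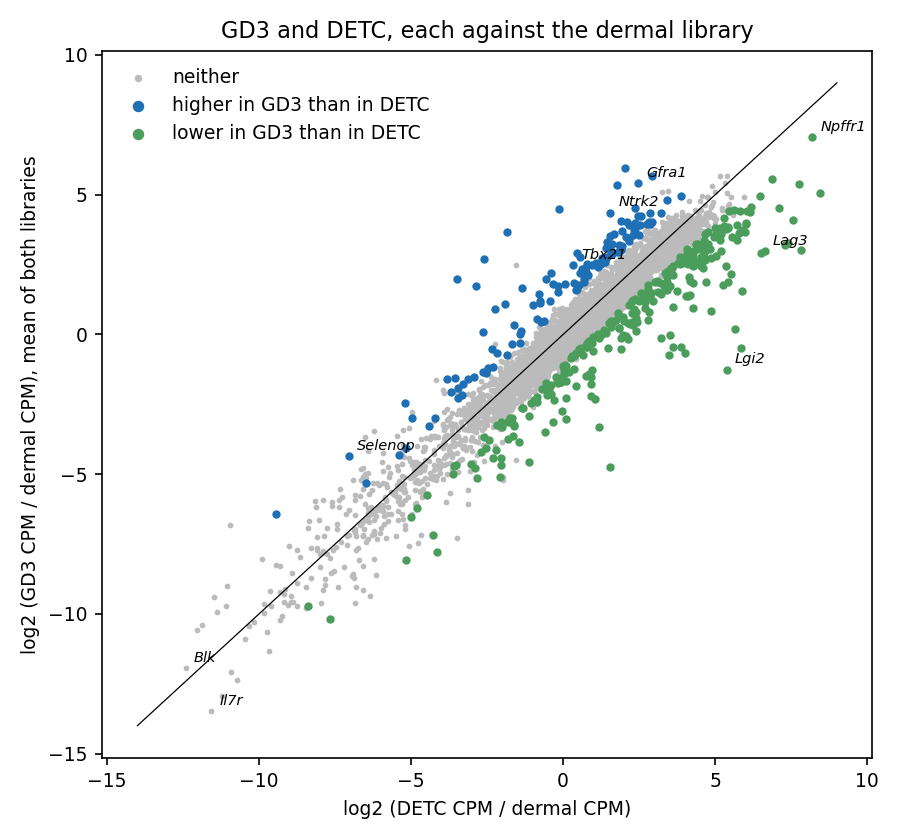
Log2 ratio of mean GD3 CPM to dermal CPM (vertical axis) against the log2 ratio of DETC CPM to dermal CPM (horizontal axis), 1 point per gene with at least 50 UMIs in any library, with a line of equality. The 121 genes higher and 278 lower in GD3 than in DETC are coloured, among them Gfra1 and Ntrk2 above the line and Lgi2 and Lag3 under it.

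Use of TCR variable genes, which took no part in the clustering, described the sorted cells. In DETC, Tcrg-V5 (ENSMUSG00000076747, chromosome 13, 19192278 to 19192725, plus strand) was the dominant γ variable gene in 88.2% (87.5 to 88.9) of 7673 cells with a γ variable UMI, and Trdv4 (ENSMUSG00000076867, chromosome 14, 54074905 to 54075515, plus strand) the dominant δ variable gene in 96.3% of 7421. These are the variable genes of the canonical DETC receptor. GD3 cells were mixed: Tcrg-V4 was dominant in 31.4% and 32.1% of A and B, Tcrg-V7 in 11.2% and 10.9%, Tcrg-V6 in 7.10% and 6.79%, Trgv2 in 6.05% and 6.88% and Tcrg-V5 in 1.52% and 1.61%. No γ variable gene was dominant in 42.1% of 6312 and 40.8% of 7022 such cells. Of δ genes, Trdv2-2 (ENSMUSG00000076866) was dominant in 45.5% and 42.0% of GD3 A and B, Trdv4 in 27.7% and 29.9% and Trdv5 in 7.63% and 7.38%. In dermal cells Tcrg-V6, typical of type 17 γδ T cells of skin and mucosa, led with 33.3% (31.8 to 34.8) of 3913 cells, followed by Trgv2 with 13.4% and Tcrg-V4 with 10.2%, while 39.6% had no dominant gene. Trdv4 was dominant in 63.5%, Trdv5 in 26.0% and Trdv2-2 in 6.47% of 4189 dermal cells.

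In summed UMIs, Tcrg-V5 held 92.5% of γ variable UMIs in DETC, Tcrg-V4 40.9% and 41.6% in GD3 A and B, and Tcrg-V6 50.9% in dermal cells. Of δ variable UMIs, Trdv4 held 99.3% in DETC and 89.6% in dermal cells, and also led in GD3 A and B with 47.8% and 50.6% against 40.9% and 36.3% for Trdv2-2, unlike the count of cells. Tcrg-V5 stood at 2536 CPM in DETC against 32.5 and 30.1 in GD3 and 44.2 in dermal cells, and droplets without cells held 1978 CPM of it in DETC and 17.96 to 31.3 elsewhere. Tcrg-V7 was 44.2- to 47.4-fold, Tcrg-V4 8.01- to 8.18-fold, Tcrg-V6 3.08- to 3.24-fold and Trdv2-2 39.9- to 50.4-fold higher in GD3 than in DETC, and Trdv4 21.9- to 23.2-fold and Tcrg-C1 3.05- to 3.10-fold lower. Of the γ variable list 3 members were higher and 2 lower of 7 in GD3 against DETC (median log2 fold 0.30), 2 and 1 against dermal cells (-0.52), and 1 and 4 in DETC against dermal cells (-1.24). The γ constant list gave 0 and 1 of 3 (-0.19), 0 and 1 of 3 (-0.26) and 0 and 0 of 3 (0.37) in the same order, and the δ list 2 and 1 of 6 (1.15), 1 and 2 of 6 (-0.21) and 1 and 3 of 5 (-1.40). Requiring 100% in place of 80% dominance lowered the DETC share of Tcrg-V5 to 56.0%, and 50% raised it to 98.7%.

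**Figure D4:**
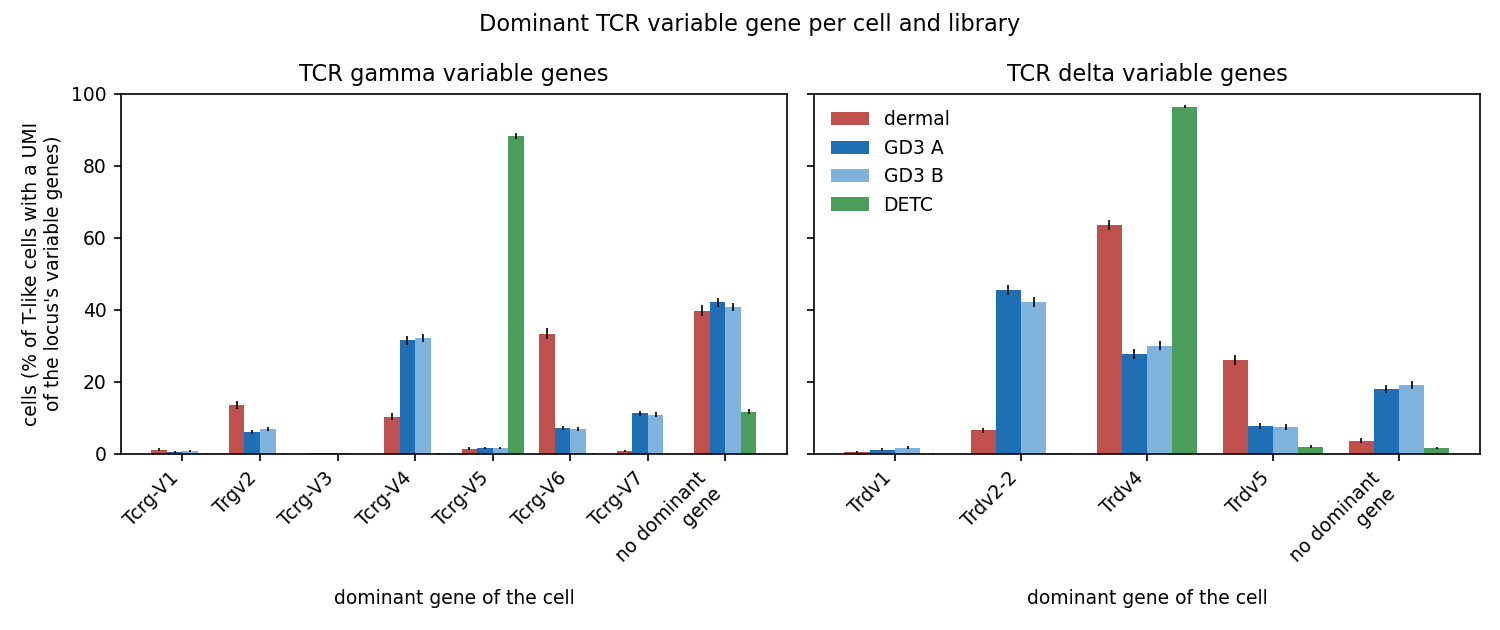
Share of T-like cells (vertical axis, percent of cells with a variable gene UMI of the locus) by dominant TCR γ (left) and δ (right) variable gene in each library, with exact 95% binomial intervals for counting error as error bars. By cells, Tcrg-V5 and Trdv4 led in DETC (88.2% and 96.3%), Tcrg-V4 and Trdv2-2 in GD3 A (31.4% and 45.5%), and Tcrg-V6 and Trdv4 in dermal cells (33.3% and 63.5%).

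Cells within a library were compared by their γ variable gene, Tcrg-V6 against Tcrg-V4, over genes of the fixed lists. In dermal cells, 15 of 250 measured list genes were higher and 17 lower in the 1304 Tcrg-V6 cells than in the 400 Tcrg-V4 cells. Cd163l1 (ENSMUSG00000025461, chromosome 7, 140218267 to 140231145), a scavenger receptor gene, stood at 1506 against 243 CPM, 6.21-fold higher (5.68 to 6.80), and the neighbouring 5830411N06Rik (140247284 to 140300736), a gene of the same family, at 14.0 against 917 CPM, 65.5-fold lower (53.3 to 81.5). The transcription factor gene Zbtb16, which encodes PLZF, was 4.19-fold, Pdcd1 4.14-fold, Ltb4r1 4.11-fold and Cxcl2 4.004-fold higher in Tcrg-V6 cells, and Cd6 had a ratio of 15.5 (4.19 to 130) from 2 Tcrg-V4 UMIs. Ccr8 was 9.93-fold, Fyb 7.46-fold, Il17f 6.37-fold (180 against 1145 CPM), Slamf1 3.61-fold and S1pr1 3.44-fold lower. Of the 400 Tcrg-V4 cells 25 lay in GD3-dominated clusters, and of the 1304 Tcrg-V6 cells 18. Dermal-library cells there held Fyb at 220 CPM, against 42.9 CPM in dermal-dominated clusters, so part of the Fyb difference may come from them. Genes were named here by a rule set after the values were seen, up to 6 per direction with at least 100 UMIs.

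The same classes were compared in GD3. Of 217 measured list genes in A 0 were higher and 7 lower in 448 Tcrg-V6 cells than in 1984 Tcrg-V4 cells, and of 219 in B 0 and 1, in 477 and 2256 cells. With dominance at 50% the lower genes numbered 4 in A and 4 in B. Whether the classes differ more in dermal cells than in GD3 was not tested, and the minimum of 50 UMIs equals 7.44 CPM in dermal Tcrg-V6 cells against 24.4 and 23.9 in GD3 A and B, and 23.98 CPM in dermal Tcrg-V4 cells against 5.02 and 4.69. Tbx21 was lower in Tcrg-V6 cells in both libraries, 2.80-fold (1.63 to 5.23) in A and 3.16-fold (1.88 to 5.74) in B, and in A Gzmb, the granzyme B gene, was 3.68-fold, Gpr55 2.21-fold and Fasl 2.04-fold lower. Blk and Il7r had 0 UMIs in all 4 of these GD3 classes, which allows up to 0.371 and 1.80 CPM in the Tcrg-V4 and Tcrg-V6 cells of A and 0.346 and 1.77 CPM in those of B.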

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

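All tests in this part were chosen after the clusters were seen. A signal outside the population analysed came from cells in clusters that were not T-like: 0.668% of dermal, 0.843% of GD3 A, 0.588% of GD3 B and 0.478% of DETC cells, where 0 cells would allow up to 0.0794%, 0.0493%, 0.0434% and 0.0477%. Cluster 15 (84 cells, median 17408 UMIs against 4398 in T-like cells) held 56962 CPM of keratinocyte markers against 178 in T-like cells, led by Krt10 at 12362 CPM, and 610 CPM of T cell markers against 13822. Cluster 16 (73 cells, median 5805 UMIs) held 9914 CPM of fibroblast markers, 996 CPM of endothelial markers and 6158 CPM of T cell markers, with Selp at 1828 and Eln at 1244 CPM. Cluster 18 (24 cells, median 4441 UMIs) held 4958 CPM of keratinocyte markers beside 12691 CPM of T cell markers, with Scd1 at 2918, Fa2h at 1281 and Elovl3 at 917 CPM. The clusters stayed unnamed, and doublets with T cells were not ruled out.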

How the results depend on the processing

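The removal of the top 6% of Scrublet scores, the Tcrg-V5 gate, the removal of proliferating clusters and all alternatives for classes within a library and for δ shares were chosen after the data were seen. Of the values of gene counts under the alternatives 146 stayed within 1.5 times the main count and 23 did not. Il3 levels stayed within their counting interval in 52 and left it in 4, γ shares in 35 and 13 and other variable gene shares in 163 and 35. List medians were held to a fixed log2 tolerance or the spread of GD3 A and B, whichever was larger, and stayed in 699 and moved in 82. Named folds were judged likewise in the GD3 comparisons and by counting interval in DETC against dermal. They stayed in 1206 and moved in 295, and 1 list median and 1 named fold turned direction. Class counts stayed in 62 and moved in 4, and class folds in 179 and 8.

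Between GD3 A and B, 11 genes passed the rule in the main setting, 110 with all called cells, 22 in cells with a Trdc UMI, 2 in thinned cells, 82 and 0 with rule minima of 20 and 200 UMIs, and 1 with the 3-fold rule. Thinned cells gave 78 genes higher and 179 lower in GD3 than in DETC, 50 above both and 41 under both populations, with fewer UMIs by construction. A minimum of 200 UMIs, which tests fewer genes, gave 68, 150, 46 and 35, and a minimum of 20 gave 112 under both. The stricter 3-fold rule gave 53 higher and 113 lower in GD3 than in DETC, 1166 and 952 against dermal cells, 1338 and 900 in DETC against dermal cells, 35 above both and 26 under both. With 1 GD3 library left out, GD3 against DETC gave 138 to 151 higher and 346 to 359 lower, GD3 against dermal 1958 to 1988 and 1652 to 1656, above both 93 to 100 and under both 95 to 106, and DETC against dermal stayed at 2198 and 1404, since it uses no GD3 library.

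Il3 fell from 0.671 to 0.251 CPM in GD3 B in cells with a Trdc UMI and to 0.408 CPM in thinned cells, from 0.347 to 0.173 CPM in GD3 A without the top 6% of Scrublet scores, and from 0.280 to 0.127 CPM in DETC without proliferating clusters; it rests on 5 to 7 cells per library, and the cause was not tested. Dominance at 50%, dominance at 100% and thinned cells gave Tcrg-V5 shares in DETC of 98.7%, 56.0% and 85.7%, Tcrg-V4 shares of 41.9%, 29.0% and 36.3% in GD3 A and 42.0%, 30.0% and 38.7% in GD3 B, and Tcrg-V6 shares in dermal cells of 44.8%, 27.04% and 41.9%, with 34.9% for the last in cells with a Trdc UMI at the main dominance. List genes lower in Tcrg-V6 than in Tcrg-V4 cells numbered 4 in GD3 A and 4 in GD3 B at 50% dominance, and 2 in GD3 B in cells with a Trdc UMI and 2 without proliferating clusters. The cell cycle median in DETC against dermal went from 0.20 to -0.36 without the proliferating clusters, and the log2 fold of Col6a2 in GD3 against dermal to -0.78 with all called cells. That setting adds only the cells outside the T-like clusters, so the turn of Col6a2 came with those cells. Which of them held Col6a2 was not tested. No paired analysis was possible because dermal cells and DETC have 1 library each.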

Other observations

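In the patterns below, the tests of depth and of cluster 7 were set before their results were seen, and the tests of the Tcrg-V5 and Trdv4 pair, of carried-over cells, of free RNA and of doublets were chosen after results were known, in part in place of others. A test of doublet scores, set beforehand for the Trdv5 cells, was dropped after its result was known. Other genes were looked up in the 12 GD3 cells with an Il3 UMI, 8 genes picked by hand, named here after their values were seen and not tested as a group. Summed over these cells, Xcl1 stood at 6465 CPM against 416 in the 15855 GD3 cells without an Il3 UMI, Il2 at 306 against 12.8 (19 UMIs in 33.3% of these cells), Csf2 at 80.4 against 16.2 (5 UMIs), Nr4a2 at 2831 against 881, Il13 at 1673 against 67.4, Areg at 9714 against 3499, Tnf at 450 against 103 and Nr4a1 at 1850 against 162.

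Il3 UMIs of the GD3 libraries lay in cells that also held Il13 UMIs: 10 of 12 (83.3%, 51.6 to 97.9) against 20.3% of the other cells. Depth as the whole cause is argued against by cells of the same library drawn to the same depth, which held Il13 in 21.25% (median 4840 UMIs in Il3-positive cells, 4428 in the others). Free RNA, which would leave single UMIs, is made less likely by 9 of 12 cells (75.0%, 42.8 to 94.5) with at least 2 Il3 UMIs. Cluster 7 held 7 of the 12 cells and 8.96% of all GD3 cells, but its other cells held Il13 in 30.6%, under the interval of its Il3-positive cells (6 of 7, 85.7%, 42.1 to 99.6). This speaks only against membership of cluster 7 as the whole cause. It cannot decide on a stronger activation of these few cells, since a cluster is a coarse measure of it. All genes looked up above stood higher in the Il3-positive cells, so stronger activation stays open. Another hypothesis that stays open is that both cytokine genes were transcribed in the same cells, for which the design has no group and which rests on 12 cells. Over all libraries 13 of 17 Il3-positive cells (76.5%, 50.1 to 93.2) held Il13, so the pattern was not seen in the GD3 libraries alone.

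DETC-library cells with dominant Trdv5 lay mostly in GD3-dominated clusters, 136 of 148 (91.9%, 86.3 to 95.7), against 695 of 7147 (9.72%) with dominant Trdv4. Cells of the GD3 sort in this library are argued against by their γ chain: 121 of the 136 (89.0%, 82.5 to 93.7) had dominant Tcrg-V5, with a median of 8 Tcrg-V5 UMIs against 10 in Trdv4 cells. Free RNA or reads of the overlapping Trdc would scatter over all cells, yet 81 of 87 cells with at least 3 Trdv5 UMIs (93.1%, 85.6 to 97.4) lay there and 21 of 7147 Trdv4 cells had as many, and Trdv4 cells drawn to the same depth lay there in 9.93%. The hypothesis that the Tcrg-V5 and Trdv4 pair goes with the DETC cluster profile in any sort was set to need at least 50% of such GD3 cells there and to fall with an upper bound under 20%, a limit that was moved to 50% and back and was first set when the number of Tcrg-V5 cells in these clusters had been seen. In DETC-dominated clusters lay 12 of 60 (20%, 10.8 to 32.3), between these limits, against 2 of 62 among other Tcrg-V5 cells, so this stays open. That the δ chain goes with the state of Tcrg-V5 cells in the epidermis may be worth following up, as a hypothesis found and tested on the same data, with no group in the design that tests it.

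In the dermal library 290 cells (6.29%, 5.603 to 7.03) lay in GD3-dominated clusters, with Cd7 at 4065 CPM against 144 in dermal-dominated clusters and Trdc at 328 against 443. The 12 genes named as highest in dermal cells over GD3 summed to 5.08 CPM (2.04 to 10.5) against 3032. This cannot decide on doublets with dermal cells. The cells were grouped by expression and the genes picked from the same libraries, so doublets with these genes would hardly have been placed here. Cells of the DETC sort would bring Tcrg-V5, dominant in 7 of 240 (2.92%, 1.18 to 5.92). Cells of the GD3 sort as the whole source are argued against by Trdv2-2, dominant in 12 of 127 (9.45%, 4.98 to 15.9). In GD3 A and B it was dominant in 44.5% of 4067 and 41.4% of 4498 cells of these clusters with a δ variable UMI. A part could still come from that sort. Other variable genes gave no single direction. Tcrg-V7 was dominant in 10.0% of the 240, near the 11.2% and 10.9% of all GD3 A and B cells, and in 0.219% in dermal-dominated clusters. Tcrg-V4 was dominant in 10.4%, against 31.4% and 32.1% in GD3 A and B and 10.3% in dermal-dominated clusters. Tcrg-V1 was dominant in 21 of the 240 (8.75%, 5.50 to 13.1), against 0.491% and 0.797% in all GD3 A and B cells and 0.602% in dermal-dominated clusters. Trdv1 was dominant in 8 of 127 (6.30%, 2.76 to 12.03), against 1.14%, 1.64% and 0.198% in the same order. The shares of Tcrg-V1 and Trdv1 thus lay above those of GD3 cells and of dermal-dominated clusters. That the dermal sort itself held such cells stays open and was not tested.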
